A study of Rattus norvegicus with 4 samples.

How the data were processed

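The measurements came from 4 2-colour oligonucleotide arrays of PCCl3 cells, an established rat thyroid follicular cell line. Per the labels' protocols, cells carrying an inducible construct were split into 2 pools and kept for 10 days with or without doxycycline, which shuts the construct off. The label on RNA extraction gives a week without the drug. Total RNA was taken at 50 % confluency, amplified, labelled with Cy5 or Cy3, and hybridized in pairs to a rat array of 70-mer probes. Each construct, Engr-HD or Engr-HDm, had 2 arrays with the dyes swapped. The expressing cells were in Cy5 on array 1 and in Cy3 on array 2, per the labels. Nothing in the labels says that the 2 arrays came from separate cultures. The p-values therefore measure only the spread between these hybridizations, which may be technical, and the number of arrays limits the precision.

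The authors deposited 1 log ratio per probe and array, which is read here as log2. The background correction, normalization, scanner software, log base and direction of the ratio were not given in the sources used here. The column medians lay within 0.003 of 0, so the values had been centred before deposit. The largest value, 5.198, exceeds 4.82, the log10 of the highest reading of a 16-bit scanner, which excludes a log10 ratio of unadjusted readings. A log10 ratio of adjusted readings and a natural log are not excluded, and with either the folds printed here would be too small. The ratio is likely expressing over non-expressing cells, because every title names the pair in that order and every array has the expressing cells in its first channel. If it ran the other way, every rise would be a fall. The relative orientation of the arrays was checked on the values. The 2 Engr-HD columns correlated at r = 0.89 over probes, so both ran the same way. The 2 Engr-HDm columns correlated at r = -0.11 (Spearman's rho = 0.195), above the limit of -0.3 fixed for turning a column. The difference between arrays 1 and 2 correlated at r = 0.849 between the constructs, so the columns of both constructs follow the dye labels in the same way. All columns were used as deposited.

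The table held 38960 rows, against 34717 probes stated for the array in the series' design. The 12 control rows, whose values stayed within 0.088 of 0, were left out, and 38948 probes were tested. Of these, 11986 carry an Ensembl rat gene ID, 24549 an Operon number beginning Rn3 and 2413 an Operon number beginning R0. The files do not pair these IDs with gene names. The reference table used here listed no Ensembl IDs for its genes, so 0 IDs could be matched to it. The 21 gene lists and the set tests fixed before the data were examined could therefore not be applied, and no gene is named. The rule for named genes asked for more members in each contrast and was cut down for probes. Named here are only the 2 largest rises and the 2 largest falls with Engr-HD. These passed the test and had the same direction on both Engr-HD arrays. Without brightness values no filter on dim probes was possible. Of the rows, 275 shared all 4 values with another row, with values of at most 0.085 in size.

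Each array was centred on its median. Ratios were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the probes tested, threshold 0.05). All 4 arrays entered 1 fit with a coefficient per construct and 2 residual degrees of freedom. The contrasts were Engr-HD against 0, Engr-HDm against 0, and Engr-HD minus Engr-HDm. Both constructs hold both dye orientations, so a dye bias of equal size on both arrays cancels in each mean but widens the spread. A part that differs in size between the 2 arrays stays in the mean. The array number marks the dye orientation, per the labels, and same-numbered arrays deviated together (r = 0.849). A fit with this number as a replicate block, which leaves 1 residual degree of freedom, was fitted as well. Other settings tried were no centring, an equal median absolute deviation, quantile normalization, robust empirical Bayes, each construct alone, the number 2 arrays turned, a threshold of 0.1, each array left out, and the dye swap taken as 1 replicate with a 2-fold minimum and no test.

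The fits were tested on simulated data for all 38948 probes, with 200 changed probes per construct. The dye bias and spread came from the fit of the real arrays with the block. In 1 version the spread was limma's estimate per probe, which is drawn towards a common prior and is not the raw spread. There the fit without the block found 58 of 66 probes changed by 1 on the log2 scale in the Engr-HD comparison. In the Engr-HDm comparison this fit found 47 of 66. It found 0 of 67 changed by 0.25 in each and called 0 unchanged probes. The fit with the block found at least 66 of 67 or 66 of 66 at every size in both comparisons. However, 98 of its 297 Engr-HD calls and 94 of its 294 Engr-HDm calls were unchanged probes. With the spread drawn from limma's own fitted prior, these were 6 of 147 and 8 of 150. In that case the fit with the block found only 10 of 67 probes changed by 0.25 with Engr-HD and 13 of 67 with Engr-HDm. The fit without it found 53 of 66 and 45 of 66 changed by 1. The simulations changed far fewer probes than the 10981 called with Engr-HD. They also gave the 2 arrays of a construct a dye bias of equal size. The shares of changed probes found and of unchanged probes called therefore cannot be carried over to the real calls.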

Results

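The transcriptome of PCCl3 rat thyroid cells was compared between cells that expressed an inducible protein and cells of the same line in which doxycycline kept it off. One protein, Engr-HD, is an antagonist of TTF1, also called Nkx2-1, the homeodomain transcription factor of thyroid, lung and forebrain. The other, Engr-HDm, is its control protein. Each construct was measured on 2 dye-swapped arrays, and each array gave 1 log2 ratio of expressing over non-expressing cells for 38948 probes. The ratios spread more widely with Engr-HD, with SDs over probes of 0.393 and 0.402 on its 2 arrays, than with Engr-HDm, with SDs of 0.146 and 0.178. The SD between the 2 arrays of a construct had a median over probes of 0.0431 for Engr-HD and 0.0467 for Engr-HDm. The files do not pair the probe IDs with gene names, so the changes are described by probe. Directions rest on the order in which the titles name each pair, which is likely but not stated for the values.

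The first comparison asked which transcripts change when the TTF1 antagonist is expressed and doxycycline withdrawn. The drug and the protein changed together, so these changes can hold either effect. The third comparison below sets them against the control protein. With Engr-HD, 5550 probes rose and 5431 fell, together 10981 of 38948 or 28.2% (limma, adjusted p below 0.05). The count was 8348 with all arrays scaled to 1 median absolute deviation, 4453 under quantile normalization, with 2392 higher and 2061 lower, and 16314 with the array number, which marks the dye orientation, as a replicate block, with 8123 higher and 8191 lower. Most of the 10981 changes were small, with a median size of 0.43 on the log2 scale, and 7553 of them were under 1.5-fold. At least a 2-fold change joined with the test left 1205 probes, 758 higher and 447 lower. For comparison, array 1 minus array 2 of Engr-HD, divided by 2, reached 2-fold at 25 probes. This quantity holds the dye bias, which cancels in each mean only as far as it is equal in size on both arrays. The quantity is therefore not a noise level for the means. By size alone and with both arrays in the same direction, rises outnumbered falls by 773 to 448 at 2-fold, 142 to 36 at 4-fold and 38 to 3 at 8-fold. At 1.5-fold the counts were 1892 and 1670. The 2-fold counts were 456 and 248 with an equal median absolute deviation and 282 and 188 under quantile normalization. Both settings draw the Engr-HD ratios towards the narrower spread of the Engr-HDm arrays.

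**Figure D1:**
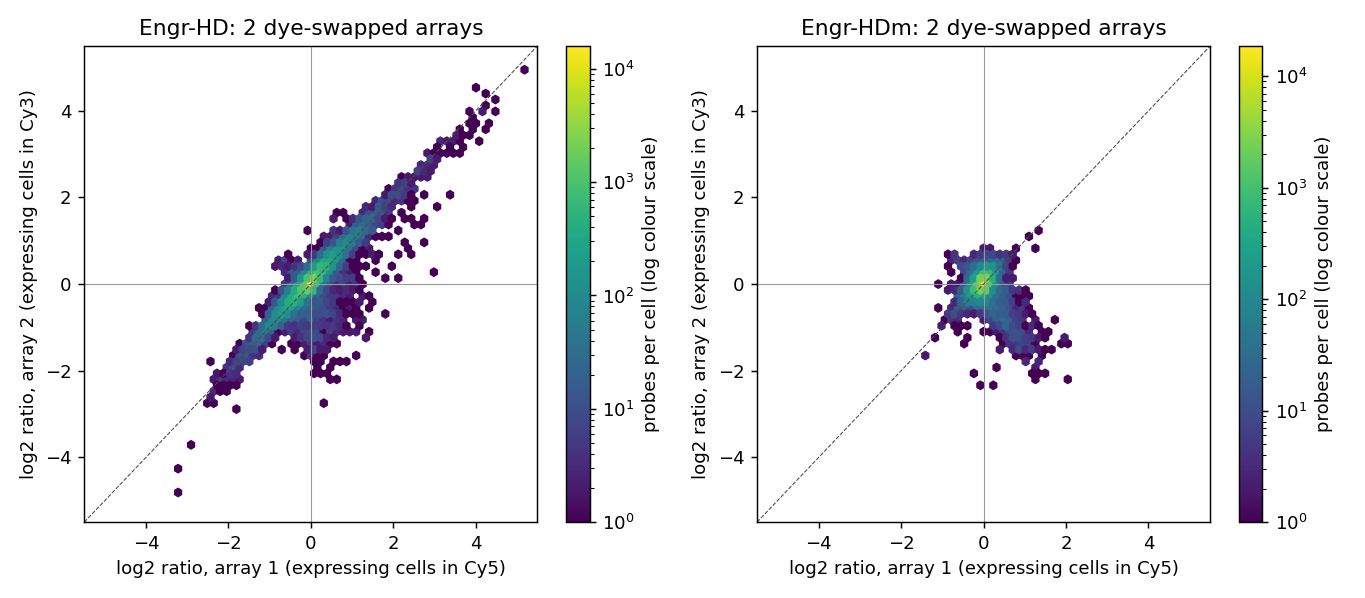
Each panel plots the log2 ratio of expressing over non-expressing cells on array 1 (horizontal) against array 2 (vertical) for 38948 probes, with colour for the number of probes on a log scale and a dashed line of equality. The Engr-HD arrays follow the line (r = 0.89), and the Engr-HDm arrays spread less and do not (r = -0.11).

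The largest rise was at probe ENSRNOG00000010233, an Ensembl rat gene ID, with a mean log2 ratio of 5.03 ± 0.23 (SD, n = 2 arrays), or 32.8-fold (limma, adjusted p = 0.000337). It stood at -0.18 ± 0.03 with Engr-HDm. The Operon probe Rn30009383 followed at 4.40 ± 0.15 (SD, n = 2 arrays), or 21.2-fold (limma, adjusted p = 0.000323), against -0.08 ± 0.13 with Engr-HDm. The means were 4.09 and 3.58 with an equal median absolute deviation and 3.32 and 2.95 under quantile normalization, and both probes still passed. Both settings give all arrays a common spread, which by construction shrinks the wider Engr-HD values. Under quantile normalization the most extreme values become averages that take in the extremes of the Engr-HDm arrays. Means under these settings, here and for the falls, are therefore not separate estimates of the fold. The largest falls were at probes Rn30005481, with a mean of -4.06 ± 1.10, and Rn30005480, with -3.73 ± 0.78 (SD, n = 2 arrays each). Their limma adjusted p-values were 0.0164 and 0.0125. With an equal median absolute deviation their means were -3.29 and -3.03, and under quantile normalization -2.98 and -2.79. These 2 probes differed strongly between dye orientations. Rn30005481 read -3.28 and -4.83 on the Engr-HD arrays and 0.39 and -1.57 on the Engr-HDm arrays. Both falls missed the threshold when either Engr-HD array was left out, with adjusted p-values from 0.0595 to 0.118, and under quantile normalization, with 0.0858 and 0.0923. With the dye orientation in the fit as a replicate block, both passed, with limma adjusted p-values of 1.51e-05 and 3.61e-05. In that fit Rn30005481 also passed as lower with Engr-HDm, at -0.59 ± 1.39 (SD, n = 2 arrays; adjusted p = 0.0166, against 0.849 without the block), and Rn30005480 did not, at -0.08 ± 1.25 (adjusted p = 0.772).

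All 3 kinds of probe held changes in both directions. Among probes with an Ensembl gene ID, 2066 rose and 1765 fell, or 32.0% of 11986. Among Operon numbers beginning Rn3, 3054 rose and 3276 fell, or 25.8% of 24549. Among those beginning R0, 430 rose and 390 fell, or 34.0% of 2413. Several probes can belong to 1 gene, so these are counts of probes and not of genes. The count past the test was 5266 without Engr-HD array 1 and 5048 without Engr-HD array 2, where the lone array was assumed to vary like those of the other construct.

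The second comparison asked what changes when the control protein is expressed and doxycycline withdrawn. With Engr-HDm, 0 probes passed the limma test, the smallest adjusted p being 0.0722, and 5440 probes had an unadjusted p below 0.05. By size alone, 3 probes were at least 2-fold higher and 6 at least 2-fold lower on average with both arrays in the same direction, and 0 reached 4-fold. The highest mean was 1.25 ± 0.03 and the lowest -1.55 ± 0.17 (SD, n = 2 arrays each). For comparison, array 1 minus array 2 of Engr-HDm, divided by 2, reached 2-fold at 118 probes, with no requirement on direction. This quantity correlated at r = 0.849 with that of Engr-HD, so much of it goes with the dye orientation. Such a bias cancels in each mean only as far as it is equal in size on both arrays. The quantity is therefore not a noise level for the means. Array 1 held 71 probes at least 2-fold higher and 6 lower, and array 2 held 2 higher and 181 lower. At 1.5-fold, with both arrays in the same direction, 14 probes were higher and 54 lower. Some dye bias may therefore remain in the Engr-HDm means, which was not tested.

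With the replicate block, 5190 probes passed the limma test with Engr-HDm, 2619 higher and 2571 lower. Of these, 5119 changed by under 1.5-fold and 10 by at least 2-fold. Each probe's dye bias, estimated in that fit over both constructs, passed the test at 3205 probes and reached 1 on the log2 scale at 62. A dye bias unequal in size between the 2 arrays would stay in the Engr-HDm means of that fit too. In simulated arrays with limma's estimate of the spread per probe, 94 of 294 Engr-HDm calls of the blocked fit were unchanged probes. With the spread drawn from limma's fitted prior, 8 of 150 were. The share of unchanged probes among the simulated calls therefore depended on how the spread was modelled. The simulations changed only 200 probes per construct, far fewer than the 5190 called here. These shares therefore cannot be carried over to the 5190, whose share of unchanged probes was not estimated.

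**Figure D2:**
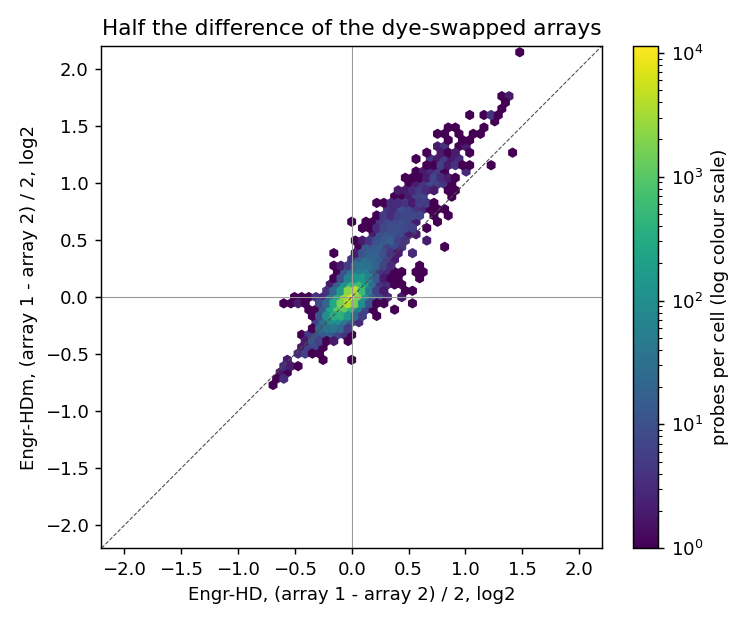
Each axis plots array 1 minus array 2, divided by 2, on the log2 scale for 1 construct, over 38948 probes, with colour for the number of probes on a log scale and a dashed line of equality. Probes deviate the same way in Engr-HD and Engr-HDm (r = 0.849 across probes).

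The third comparison set the change with the antagonist against that with the control protein. The 2 changes differed at 6656 probes (limma, adjusted p below 0.05), at 3440 of them upwards with Engr-HD relative to Engr-HDm and at 3216 downwards. The count was 4328 with an equal median absolute deviation, with 2339 upwards and 1989 downwards, 1829 under quantile normalization, with 1047 and 782, and 12891 with the replicate block. Of the 10981 probes that changed with Engr-HD, 6390 passed this test too, and a further 266 passed it without passing the Engr-HD test. Both tests use the same Engr-HD arrays, so the overlap of their calls is not independent evidence. A difference can also come from the Engr-HDm arrays. At the probe with the largest Engr-HDm rise, the mean was 1.25 with Engr-HDm and -0.01 with Engr-HD. Its difference passed too (limma, adjusted p = 0.00151). Among the 1205 probes that changed at least 2-fold with Engr-HD, the Engr-HDm mean was under 1.5-fold at 1197 or 99.3%, against 38877 or 99.8% of all probes tested. Among these 1205, the median ratio of the Engr-HDm to the Engr-HD change was 0.00718. Each array weighed on the count, which was 2267 without Engr-HD array 1, 2162 without Engr-HD array 2, 2773 without Engr-HDm array 1 and 2716 without Engr-HDm array 2.

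Probe ENSRNOG00000010233 differed by 5.21 ± 0.12 (SE) on the log2 scale between the constructs (limma, adjusted p = 0.00117) and probe Rn30009383 by 4.48 ± 0.11 (SE, adjusted p = 0.00115). These differences were 4.31 and 3.69 with an equal median absolute deviation and 3.64 and 3.10 under quantile normalization. Both settings give all arrays a common spread and so shrink the Engr-HD values by construction. For Rn30005480 the difference was -3.65 ± 0.74 (SE, adjusted p = 0.0493), which missed the threshold when any 1 array was left out, with adjusted p-values from 0.0529 to 0.194. It also missed it under robust empirical Bayes (adjusted p = 0.0689), equal scaling (-3.02, adjusted p = 0.131) and quantile normalization (-2.93, adjusted p = 0.218). With the replicate block it passed (adjusted p = 0.000195). With 1 array left out, the difference ran from -4.53 to -2.77. For Rn30005481 the difference was -3.47 ± 0.89 (SE), which did not pass (adjusted p = 0.0861), and with the replicate block it passed (adjusted p = 8.98e-05). This difference was -2.66 with equal scaling, -2.52 under quantile normalization and from -4.45 to -2.49 with 1 array left out.

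**Figure D3:**
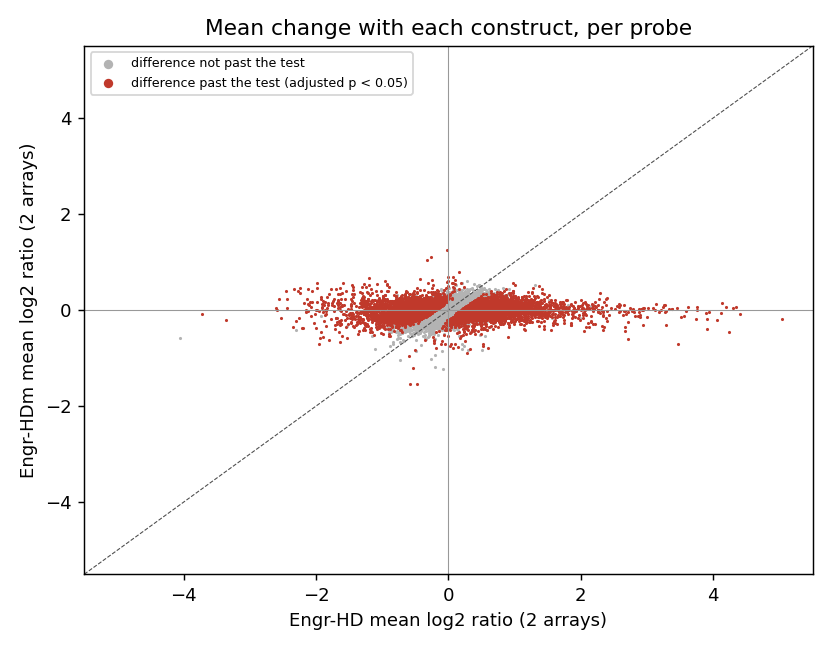
The mean log2 ratio of 2 arrays with Engr-HD (horizontal) is plotted against that with Engr-HDm (vertical) for 38948 probes, on equal scales with a dashed line of equality. Red points are the 6656 probes whose difference passed the limma test, and they spread along the Engr-HD axis.

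The changes with the 2 constructs were weakly related across probes, with r = 0.194 and Spearman's rho = 0.261 and a slope of 0.0546 of the Engr-HDm on the Engr-HD mean. Without Engr-HDm array 2, r was 0.0767. Probes are not independent replicates, so no p-value is given. Of the 10981 probes that changed with Engr-HD, 7077 or 64.4% had an Engr-HDm mean of the same sign. In the fit with the replicate block, 1482 probes rose and 1668 fell with both constructs, against 546 and 541 for independent lists. A further 501 rose with Engr-HD and fell with Engr-HDm, against 536, and 601 did the opposite, against 551. The 2 tests in that fit share 1 estimate of the spread per probe, which by itself makes their calls coincide, but in both directions alike.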

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

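The difference between the constructs was a comparison planned before the data were examined, and each result here was picked out because its change differed between Engr-HD and Engr-HDm in the limma test of that difference. In all, 6656 probes differed. Among the probes named in the report, ENSRNOG00000010233 differed by 5.21, Rn30009383 by 4.48 and Rn30005480 by -3.65 on the log2 scale. With 2 arrays per construct, no group was large enough to test for a sample far from the others.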

How the results depend on the processing

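Removing the centring, robust empirical Bayes and fitting each construct alone left the counts of changed probes within 1.5 times their values. With an equal median absolute deviation on all arrays, 2 probes passed with Engr-HDm and 4328 in the difference. Quantile normalization, which by construction gives the constructs the same spread of ratios, left 4453 with Engr-HD and 1829 in the difference. With the replicate block, 16314 passed with Engr-HD, 5190 with Engr-HDm and 12891 in the difference, and all of the 10981 and 6656 probes past the tests without it passed with it. With a threshold of 0.1, 152 passed with Engr-HDm. Taking the dye swap as 1 replicate with a 2-fold minimum and no test gave 1221 probes with Engr-HD, 9 with Engr-HDm and 1181 in the difference. Leaving out 1 array gave 5048 to 9777 with Engr-HD, 0 with Engr-HDm and 2162 to 2773 in the difference, with 1 array and 1 residual degree of freedom fewer. The correlation between the constructs ran from 0.0767 to 0.224. Turning the number 2 arrays, which by construction cancels what both arrays share and leaves the dye bias, gave 0 probes with Engr-HD and 0 in the difference and a correlation of 0.849. It also reversed Rn30005481 to 0.78 and Rn30005480 to 0.55 with Engr-HD. Of 84 values for the 4 named probes under the alternatives, 63 kept their direction and their side of the threshold. For the other counts and probes the cause was not tested. The set tests on gene lists were not run, since no probe had a gene name. Tests per probe without averaging and with a value missing were not run, since they would repeat the same probes. Brightness over background, which limits how firmly small ratios can be read, is not part of the values used here. The 2-fold minimum joined with the test was chosen after seeing the data.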

Other observations

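The tests of the dye bias, of the change shared by the Engr-HDm arrays, of rises and falls on single arrays, of a common shift and of related transcripts at consecutive probe numbers were chosen only after the results were seen. The others were written down before.

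With Engr-HDm, 0 probes passed without the dye orientation in the fit and 5190 with it. A dye bias of each probe may account for the first count, since array 1 minus array 2 correlated at r = 0.849 across probes between the constructs. Both Engr-HDm arrays may also carry changes of their own, most of them under 1.5-fold. The 2 arrays correlated at r = 0.48 once the dye bias estimated from the Engr-HD arrays alone was taken off. The 2 explanations do not exclude each other. Whether such changes come from the control protein or from doxycycline withdrawal cannot be told from these arrays, because the drug and the protein changed together.

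Large rises outnumbered large falls with Engr-HD, by 773 to 448 at 2-fold, by 456 to 248 with an equal median absolute deviation and by 282 to 188 under quantile normalization. The tables argue against a dye bias, since rises over falls was 1.44 and 1.56 on the 2 dye-swapped arrays. They also argue against transcripts with several probes, since the ratio was 1.85 (331 to 179) among Ensembl IDs, each listed once. Centring stayed undecided at 2-fold. A shift of 0.107 of the mean would make the counts equal. This is just above 0.1, the bound set beforehand above which centring was not to be taken as the cause. The single Engr-HD arrays needed shifts of 0.085 and 0.067, which lie below that bound. However, the shift needed was 0.02 at 1.5-fold and 0.328 at 4-fold, so 1 shift common to all probes does not make the counts equal at both. Centring is such a shift, so these values argue against centring alone as the cause of the excess at both sizes. A background floor that limits falls more than rises stays open without brightness values, as does an effect of the antagonist itself, and the sign of the whole pattern rests on the likely direction of the ratios.

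Probes with consecutive Operon numbers had more similar values than in shuffled orders. Over 22401 consecutive pairs, the Engr-HD changes correlated at r = 0.115, against at most 0.0224 in 1000 shuffled orders. Of 523 probes at 2-fold, 48 or 9.18% had the next number at 2-fold in the same direction. Of all such probes, 2.38% were at 2-fold in either direction, which is a wider measure than the same direction. The pattern was not particular to Engr-HD, since the Engr-HDm changes correlated at r = 0.115 and the dye bias at r = 0.0844 between consecutive numbers. Rn30005480 and Rn30005481, the 2 largest falls, are such a pair. A candidate explanation is that consecutive numbers are probes of the same or related transcripts, so that counts of probes exceed counts of transcripts. A local artefact of the slide cannot be told apart from it, because the residuals left after construct and dye also correlated between consecutive numbers, at r = 0.0592.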
